A study of Mus musculus with 79 samples.

How the data were processed

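RNA was measured in mouse muscle from 2 knockouts, each with its own controls, at 6 zeitgeber times (ZT, hours after lights on): 0, 4, 8, 12, 16 and 20 h. MKO stands for a muscle-specific knockout and CTRL for control mice, whose genotype the labels give as wild type. Per the labels, total RNA was extracted with an organic reagent followed by silica columns, and stranded poly-A libraries were run on a NextSeq instrument. The submitters' processing notes name bcl2fastq 2.20.0.422, Trimmomatic, STAR, MultiQC, R 4.1 and DESeq2, and the builds GRCm39 and mm9, with no role or order. The read counter, its use of strand, the annotation and which build served which step are not given in the sources used here.

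Values per library were not analysed here. The 12 tables used hold the authors' own comparisons of MKO with CTRL, 1 table per knockout and ZT, so the depth of each library is unknown and no interval from read counts is given. The precision of each value is that of the authors' error or test. The RORA tables hold, per the file headers, a mean normalized count as a signal level, a log2 fold change with its error, a p-value and an adjusted p. The deposited mean normalized count is the same in the 6 RORA tables. Per the labels' sample descriptions, the RORA fold changes are knockout over wild type, after a filter of 10 reads in 3 samples. The ratio of the deposited log2 fold change to its error was 0.779 times the z value of its p (median), as happens with shrunken fold changes. RORA sizes may thus be understated. Shrinkage need not be the same at each ZT, so differences in size between ZT may be stretched or narrowed by it. The PER2 tables hold, per the file headers, a log2 fold change, a mean log2 CPM, a likelihood ratio score and a p-value with its adjusted p. These PER2 tables give no error, and neither their headers nor the labels say which genotype is over which. PER2 values are therefore written as positive or negative deposited log2 fold changes, not as higher or lower in the knockout. An error was derived for PER2 as the size of the log2 fold change over the root of the authors' deposited likelihood ratio score. In both sets the deposited adjusted p equalled a recomputed Benjamini-Hochberg value, with a largest difference of 1.3e-14.

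The PER2 tables list 12952 genes by symbol and the RORA tables list 14253 by Ensembl identifier. Of the RORA genes, 13339 carried a deposited symbol and 893 were named through GENCODE M21, the mouse annotation at hand, which is on another build than those named in the notes. It was used for names, chromosomes, transcript length and GC content only, and no coordinates are given. By symbol 12333 PER2 genes (95.2%) matched it, and by identifier 14229 RORA genes. The 2 sets shared 11436 genes. One deposited RORA p-value was exactly 0 and was read as a z of 37.0.

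At each ZT a gene was called when the authors' deposited adjusted p was under 0.05. For the mean over the 6 ZT, RORA log2 fold changes were combined by an inverse-variance weighted mean, and PER2, with no deposited error, by Stouffer's sum of signed z values from the deposited p. Both used a two-sided normal p. Printed means and SDs are the plain mean and SD over the 6 ZT. Change of the effect with ZT was tested by Cochran's Q with 5 degrees of freedom. The difference between the knockouts was tested on the 2 weighted means over the root of the sum of their squared errors, and so its size can depart from the difference of the plain means, as for Arntl, at 1.53 with plain means of 0.04 in PER2 and -1.77 in RORA. Each test was adjusted by Benjamini-Hochberg over all genes tested, and calls had an adjusted p under 0.05. Overlaps of calls were tested with Fisher's exact test, one-sided. In all, 39 gene lists, 27 of pathways and 12 of other cell types, were tested with camera in limma 3.58.1 (R 4.3.3) at a preset correlation of 0.01 on the 6 log2 fold changes per gene. Lists with fewer than 3 measured genes were not tested. Other computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.

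The gene lists, the tests, the alternative settings and the rule for naming genes were fixed before the data were examined. Because the tables hold comparisons and not counts, the tests set in advance for such tables were used in place of those for counts per library. The rule names the targeted gene, and clock genes past a threshold. It takes the 8 highest and 8 lowest means among calls with 1 sign at all 6 ZT, a symbol that is not a predicted name and a mean normalized count of at least 50 (PER2: at least 1 CPM). From each list past its test it takes up to 4 members with the smallest adjusted p, and from other pathway lists up to 2. For the change with ZT it takes the 6 smallest adjusted p, and for the difference between knockouts the 6 highest and 6 lowest values. Genes outside the rule are said to be so where they are named, and 2 genes that the rule takes are not reported here, though they count in their lists.

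The combining steps were tested on simulated data made from the deposited errors. Of unchanged simulated genes 0.06% were called in PER2 (12952 genes) and 0.07% in RORA (14253 genes). Genes shifted by 0.25, 0.5 and 1.0 on the log2 scale were called in 69.1%, 96.8% and 100.0% of cases in PER2 and in 95.8%, 100.0% and 100.0% in RORA. A change with ZT of amplitude 1.0 was called in 97.5% of cases in PER2 and 100.0% in RORA. A difference between knockouts of 0.25, 0.5 or 1.0 was called in 60.8%, 94.3% and 99.2%. Simulated lists of 20 genes shifted by 0.1 had an unadjusted camera p under 0.05 in 100% of 50 draws in each set. Unshifted ones had it in 4% (PER2) and 2% (RORA). The measured lists were called by an adjusted p, which is stricter. The simulated genes varied independently, so these rates do not cover lists whose members move together. Their noise was drawn from the same errors that the tests use, so the rates cannot show whether those errors are right. Shifts were added on the deposited scale, which may be shrunken in RORA.

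Combining ZT treats the 6 tables of a set as independent, since each ZT has its own mice in the labels. The errors may still be shared. The mean normalized count was the same in the 6 RORA tables, and the PER2 median derived error was 0.135 at ZT0 and 0.137 at ZT4. If the error of a gene were too small at every ZT, its combined p would be too small as well, which was not tested. Among genes far from the threshold (adjusted p over 0.5) the median Q of the z values was 4.56 in PER2 and 6.14 in RORA, where independent tables would give 4.35. In RORA these genes thus spread more between ZT than their p-values allow for. Whether by change with ZT or by errors that are too small was not tested. Alternatives tried were a random-effects mean, limma on the 6 values per gene, leaving out each ZT, a floor on expression, a size minimum of 1.5-fold, a 24 h cosine, an estimated correlation or ranks in camera, and a stricter threshold for overlaps. Chosen after the data were seen were a PER2 mean without ZT4 and ZT12, PER2 fold changes corrected for transcript length and GC content, a PER2 mean with the derived error, Q on z values, Stouffer's sum for both sets of calls in the overlap, the counts of list members whose effect changed with ZT, and the PER2 sign reversed. The rhythm of the controls was not tested, since no values per library or group were used.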

Results

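The data set holds 79 RNA-seq libraries of mouse muscle from 2 knockouts of clock-related transcriptional regulators. PER2 is a repressor of the circadian clock, and RORα, encoded by Rora, is a nuclear receptor that drives transcription of the clock gene Arntl. The PER2 set has 24 MKO and 19 CTRL libraries, and the RORA set 18 MKO and 18 CTRL libraries. Each genotype has 3 or 4 libraries at each ZT, each from a separate mouse by the study's design text. The design asks what the loss of each factor does to the muscle transcriptome through the day, and how far the effects of the 2 knockouts differ. Fold changes are the authors' log2 values. Unless said otherwise, a value is the mean ± SD over the 6 ZT comparisons of a set (n = 6 ZT), so the SD holds both time of day and sampling error. The depth of the libraries is unknown.

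The targeted genes were examined first. In the RORA set, Rora fell by 1.78 ± 0.15. In the authors' deposited tables it was called at each of the 6 ZT, from -1.51 at ZT4 to -1.96 at ZT8. In the PER2 set, Per2 had a mean deposited log2 fold change of 0.37 ± 0.29, positive at 5 of the 6 ZT, with an adjusted p of 0.000451 by Stouffer's sum (0.1 without ZT4 and ZT12, and 0.0587 by limma). In the authors' deposited tables it was called at ZT12 alone (0.70, adjusted p 0.0418), and stood at -0.16 at ZT0. The direction of the PER2 tables is not stated. Read as knockout over control, Per2 transcript was not lowered in the knockout. Read the other way, it was lower by the same amount. A gene-level value can include transcripts that lack a deleted exon, so neither reading settles the direction.

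Expression of much of the muscle transcriptome differed between RORA MKO and CTRL at every ZT. The labels give CTRL as wild type, so other differences between MKO and CTRL mice cannot be told from the loss of RORα. Among the 14253 genes, the authors' deposited adjusted p called 4012 at ZT0 (2104 up, 1908 down), 4134 at ZT4, 3956 at ZT8, 3147 at ZT12, 2947 at ZT16 and 4591 at ZT20 (2367 up, 2224 down). Across ZT, 563 genes were called up and 668 down at all 6 ZT. The fold changes of any pair of ZT correlated across genes with Pearson's r between 0.811 and 0.886, where genes are not independent replicates. The mean over ZT passed the threshold for 5449 genes (2694 up, 2755 down), of which 4112 had the same sign at all 6 ZT. Most changes were small, with a median size of 0.14 among calls, and 180 genes changed by at least 1 on the log2 scale.

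**Figure D1:**
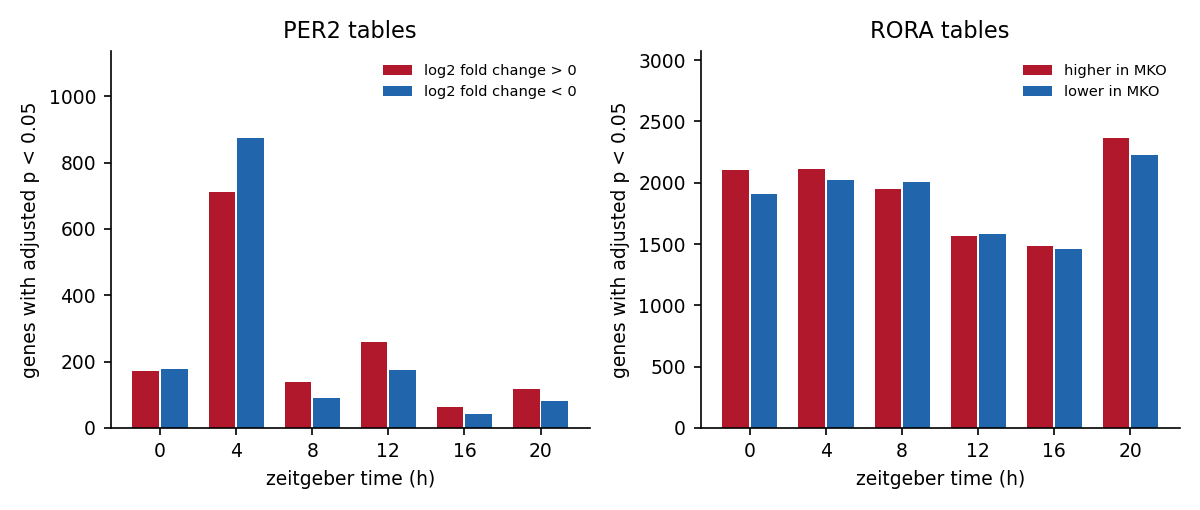
Number of genes with a deposited adjusted p under 0.05 (vertical axis) at each zeitgeber time in hours (horizontal axis), for the PER2 tables on the left and the RORA tables on the right, on separate scales. Red bars count positive and blue bars negative log2 fold changes. PER2 calls stand at 1586 at ZT4 and between 105 and 432 at the other ZT, and RORA calls between 2947 and 4591.

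Among genes with a mean normalized count of at least 50, 1 sign at all 6 ZT and a name that is not a predicted one, those that fell most in RORA MKO were Htra4, a serine protease (-4.38 ± 0.31), Pla2g7, a secreted phospholipase that inactivates platelet-activating factor (-3.69 ± 0.29), and Stab2, a scavenger receptor for hyaluronan (-3.17 ± 0.12). Next came Ostn, which encodes the muscle-secreted peptide musclin (-2.45 ± 0.31), Mss51 (-2.35 ± 0.21), the adaptor Shc2 (-2.31 ± 0.37), the integrin subunit Itga4 (-2.19 ± 0.24) and Odf3l2 (-2.13 ± 0.79). Those that rose most, under the same limits, were Ighm, the immunoglobulin mu heavy chain (2.13 ± 0.39), the antisense transcript Srrm4os (1.81 ± 0.40), the mitotic kinase Aurka (1.79 ± 0.16) and the lipid transporter Abca4 (1.54 ± 0.10). They were followed by the cytokine Il15 (1.48 ± 0.21), Tph1, an enzyme of serotonin synthesis (1.44 ± 0.34), the glycogen-binding protein Stbd1 (1.44 ± 0.18) and the lipid droplet coat protein Plin3 (1.41 ± 0.09). Each of these 16 genes was called at all 6 ZT, and the largest adjusted p of the inverse-variance mean was 1.55e-165 among those that fell and 1.38e-53 among those that rose. Srrm4os is uncertain, since the use of strand in counting is not given, and immunoglobulin genes share sequence with their relatives.

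Most of the clock genes that changed in RORA MKO fell. Arntl, which encodes the clock activator BMAL1, fell by 1.77 ± 0.77, and Cry1, a clock repressor, by 0.66 ± 0.31. The repressors Nfil3 (-0.54 ± 0.14), Bhlhe41 (-1.25 ± 0.22) and Nr1d1, which encodes REV-ERBα (-0.69 ± 0.36), fell, as did Nr1d2 (-0.25 ± 0.14), Cry2 (-0.33 ± 0.07) and the output factors Hlf (-1.01 ± 0.24) and Dbp (-0.29 ± 0.14). Tef (0.14 ± 0.08) and the deubiquitinase gene Usp2 (0.12 ± 0.08) rose. In the list of clock activators and genes in phase with Arntl, 1 of 7 rose, 4 fell and 2 did not pass, and 5 passed when adjusted over the list alone. The 4 that fell include Rora, the targeted gene. In the list of clock repressors and output genes, 2 of 13 rose, 6 fell and 5 did not pass, with 8 past the threshold adjusted over the list alone. Clock itself stood at 0.03 ± 0.06 and Per1 at 0.08 ± 0.12, neither past the threshold. As groups, neither clock list passed camera (adjusted p 0.134 and 0.146).

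Genes of mitochondrial energy metabolism rose in RORA MKO. Of 25 nuclear-encoded genes of oxidative phosphorylation, 24 rose and 1 fell, among them the ATP synthase subunits Atp5b (0.26 ± 0.06) and Atp5o (0.27 ± 0.04), Uqcrc1 of complex III (0.22 ± 0.04) and Cox4i1 of complex IV (0.21 ± 0.04). The camera test gave this list an adjusted p of 4.47e-10 (adjusted p = 0.558 with an estimated correlation in place of the preset one), and 25 members passed adjusted over the list alone. Of 14 genes of the tricarboxylic acid cycle, 12 rose and 1 fell (adjusted p 1.34e-05, and adjusted p = 0.558 with an estimated correlation, 14 past the threshold adjusted over the list alone), with Idh3a at 0.31 ± 0.07 and Sucla2 at 0.26 ± 0.07. Pcx, the pyruvate carboxylase gene that feeds the cycle, fell by 0.56 ± 0.10.

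Of 22 genes of fatty acid oxidation, 16 rose and 3 fell in RORA MKO (adjusted p 0.0265, and adjusted p = 0.874 with an estimated correlation), with 20 past the threshold adjusted over the list alone. The effect changed with ZT for 17 of the 22, and the list median went from 0.22 at ZT0 and ZT8 to 0.03 at ZT12 and -0.04 at ZT16, where 1 gene was called up and 4 down in the authors' deposited tables. Cpt2 of the mitochondrial carnitine shuttle (0.22 ± 0.12), Eci1 (0.19 ± 0.10) and Eci2 (0.13 ± 0.08) rose, and the acyl-CoA synthetase Acsl1 fell by 0.24 ± 0.18. In the list of lipid uptake and storage, 9 of 17 rose and 1 fell (adjusted p 0.045, and adjusted p = 0.77 with an estimated correlation), 11 of them past the threshold adjusted over the list alone. Gpam, which starts triglyceride synthesis, rose by 0.34 ± 0.17 and the droplet protein Plin4 by 0.42 ± 0.15, while the lipoprotein receptor Vldlr fell by 0.43 ± 0.05. Markers of endothelial cells rose beside these metabolic lists, 10 of 12 (adjusted p 0.00545, and adjusted p = 0.612 with an estimated correlation, 12 past the threshold adjusted over the list alone). The fatty acid oxidation call was lost without ZT0 (adjusted p 0.0727) or ZT8 (0.0684), and the lipid call without ZT0 (0.0643), ZT8 (0.0861), ZT12 (0.0501) or ZT20 (0.0512). Among the endothelial genes were Cdh5 (0.17 ± 0.11), Pecam1 (0.16 ± 0.10), Tie1 (0.19 ± 0.09) and Egfl7 (0.16 ± 0.11).

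Genes of excitation-contraction coupling and fast fibres fell in RORA MKO. Of 16 genes of excitation-contraction and calcium handling, 12 fell and 3 rose (adjusted p 0.000677, and adjusted p = 0.558 with an estimated correlation). They included Mrln, a micropeptide regulator of the calcium pump SERCA (-0.85 ± 0.08), Asph (-0.73 ± 0.08), Jph2, which tethers the sarcoplasmic reticulum to the T-tubule (-0.53 ± 0.12), and triadin, Trdn (-0.38 ± 0.10). Adjusted over the list alone, 15 passed. Of 14 genes of the fast sarcomere, 9 fell and 1 rose (adjusted p 0.0113, and adjusted p = 0.56 with an estimated correlation, 11 past the threshold adjusted over the list alone). Actn3 (-0.24 ± 0.13), Tnnc2 (-0.19 ± 0.07) and Tnni2 (-0.15 ± 0.05) fell, and Mylpf rose by 0.17 ± 0.13. Of 24 cytosolic ribosomal protein genes, 14 fell and 0 rose (adjusted p 0.00563, and adjusted p = 0.612 with an estimated correlation, 15 past the threshold adjusted over the list alone), by small amounts such as -0.16 ± 0.05 for Rpl5, -0.15 ± 0.04 for Rps4x, -0.10 ± 0.04 for Rpl4 and -0.09 ± 0.03 for Rpsa. Ribosomal protein genes have many processed copies in the genome, which can take part of their reads. With an estimated correlation camera called 0 of the 37 lists tested in RORA, and 0 had an unadjusted p under 0.05 (smallest 0.0503).

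**Figure D2:**
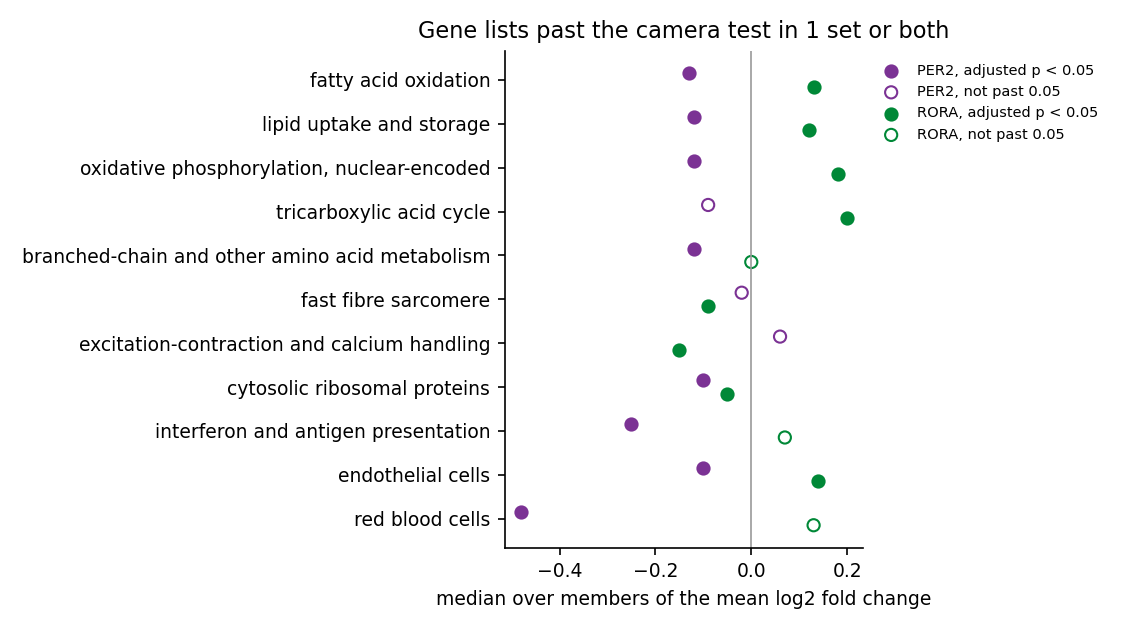
Median over the members of a gene list of the mean log2 fold change over 6 ZT (horizontal axis), for each list past the camera test in at least 1 set (vertical axis). Purple marks PER2, in the deposited direction, and green RORA. Filled points have an adjusted p under 0.05 and open points do not. Nuclear oxidative phosphorylation genes lie at 0.18 in RORA and at -0.12 in PER2.

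The effect in RORA MKO differed between ZT for 1565 genes (Cochran's Q, adjusted p under 0.05). Each ZT has its own mice, so Q cannot tell time of day from differences in the mice or tissue sampled at a ZT. Of the 1565 genes, 842 had 1 sign at all ZT and 723 had both. Arntl led them (adjusted p 2.4e-30): in the authors' deposited tables it was lower by the least at ZT0 (-0.80) and by the most at ZT12 (-2.65). The ubiquitin ligase genes Trim63 (MuRF1) and Fbxo32 (atrogin-1), which mark muscle atrophy, followed (adjusted p 1.31e-22 and 4.2e-21). In the authors' deposited tables Trim63 was at 0.19 at ZT12 and -0.32 at ZT16, and Fbxo32 at -0.20 at ZT8 and -1.08 at ZT16. The RNA-binding protein gene Cpeb1 (-0.89 at ZT0, -0.18 at ZT12), Odf3l2 (-3.30 at ZT8, -1.25 at ZT16) and the cadherin Cdh4 (-1.87 at ZT0, -0.04 at ZT12) completed the 6 smallest adjusted p, with values from the authors' deposited tables. A cosine of 24 h called 772 genes, and 609 of the 1565 were among them. Q on z values from the deposited p, which does not use the sizes, called 2617. Uneven shrinkage may stretch differences in size between ZT for some genes. At ZT8 Cdh4 was at -0.43 with an error of 0.22 and a deposited adjusted p of 0.0041, smaller than that ratio gives. Markers of other cell types were among the 1565, with 5 of 10 Schwann cell, 5 of 12 endothelial and 2 of 8 white adipocyte genes. Fibroblast markers had 0 of 16 and macrophage and leukocyte markers 0 of 14. Over all lists of other cell types it was 15 of 98, beside 11.0% of all genes. Sarcomere genes were among the 1565 as well, with 5 of 12 slow and 8 of 14 fast ones. The median of the Schwann cell genes was -0.30 at ZT4 and 0.74 at ZT20, that of the white adipocyte genes -0.50 at ZT0 and 0.53 at ZT20, and that of the slow sarcomere genes 0.62 at ZT0 and -0.19 at ZT4.

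**Figure D3:**
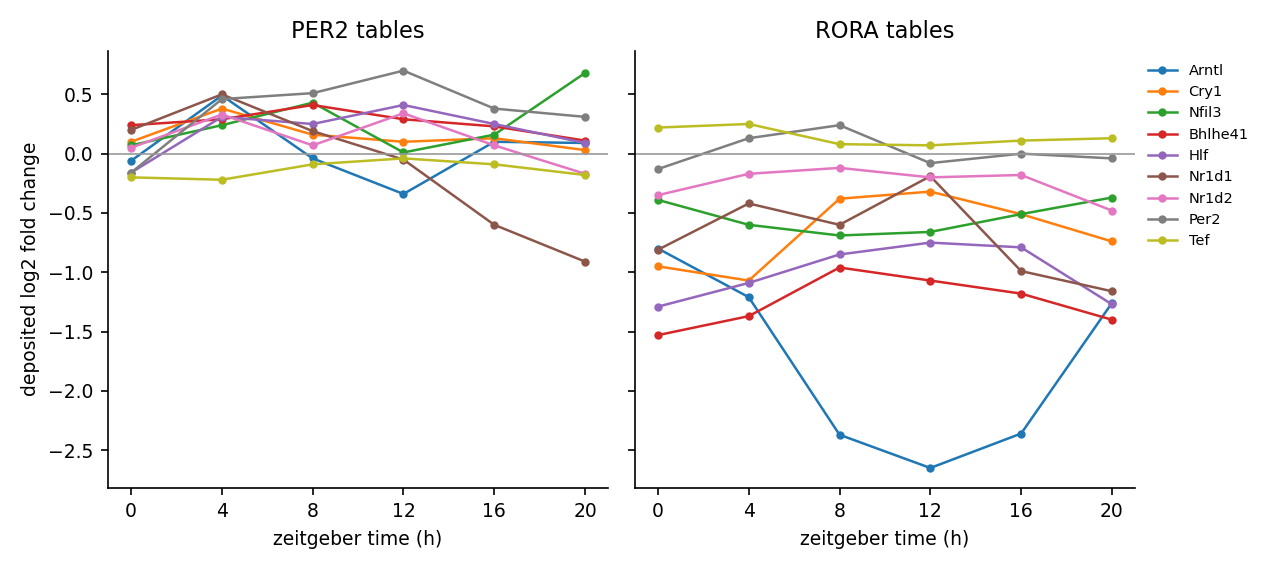
Deposited log2 fold change (vertical axis) of 9 clock genes at each zeitgeber time in hours (horizontal axis), 1 line per gene, for the PER2 tables on the left and the RORA tables on the right. RORA values of Arntl lie between -0.80 at ZT0 and -2.65 at ZT12, and PER2 values of Nr1d1 go from 0.50 at ZT4 to -0.91 at ZT20.

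In the PER2 set fewer genes were called, and most of them at ZT4. Among 12952 genes, the authors' deposited adjusted p called 350 at ZT0 (172 positive, 178 negative), 1586 at ZT4 (711 positive, 875 negative), 230 at ZT8, 432 at ZT12 (258 positive, 174 negative), 105 at ZT16 and 197 at ZT20. Across ZT, 25 genes were called positive and 19 negative at all 6 ZT, and 1519 of the 1988 genes called at any ZT were called at 1 ZT alone. The mean over ZT passed the threshold for 2792 genes (1414 positive, 1378 negative), with a median size of 0.19 and 60 genes at 1 or more in size. Without ZT4 and ZT12 the count was 1379, and with limma on the 6 values per gene, which takes the spread between ZT as the error, it was 1092.

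Fold changes at ZT4 and ZT12 in the PER2 tables went with transcript length. Across expressed genes, Spearman's rho of the fold change with transcript length was 0.52 at ZT4 and 0.44 at ZT12, and between -0.24 and 0.09 at the other ZT. With GC content it was -0.35 at ZT4 and -0.44 at ZT12. A smooth fit of length and GC content took up 24.9% of the variance at ZT4 and 22.4% at ZT12, and at most 2.7% elsewhere. With that trend removed, 705 genes were called at ZT4 and 273 at ZT12. Red blood cell genes moved at the same times: the 5 measured had a median of -1.35 at ZT4 and -1.01 at ZT12, and 5 and 4 of them were called in the authors' deposited tables. The fold changes of ZT4 and ZT12 correlated across genes at r = 0.718, and other pairs of ZT at 0.2 to 0.54.

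**Figure D4:**
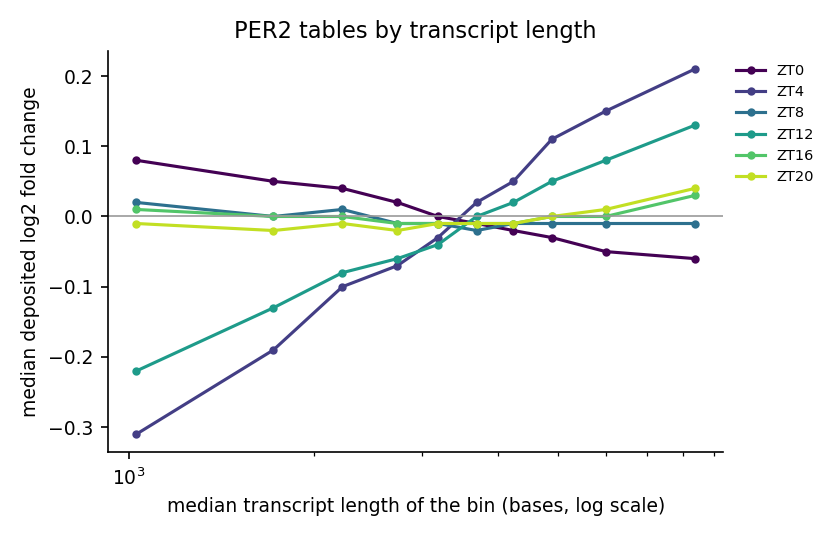
Median deposited log2 fold change of PER2 genes (vertical axis) in 10 bins of transcript length in bases (horizontal axis, log scale), 1 line per zeitgeber time. From the shortest to the longest bin the median goes from -0.31 to 0.21 at ZT4 and from -0.22 to 0.13 at ZT12.

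Among genes at 1 CPM or more with 1 sign at all 6 ZT and a name that is not a predicted one, the largest negative PER2 means were those of Ighg2c, an immunoglobulin heavy chain gene (-2.39 ± 1.13), the phospholipase Pla2g5 (-2.29 ± 0.59), the cardiac actin gene Actc1 (-1.99 ± 0.40) and the cytochrome P450 gene Cyp4f39 (-1.59 ± 0.83). The replication helicase subunit Mcm6 (-1.53 ± 0.39), Ighm (-1.37 ± 0.54), Tmem45b (-1.20 ± 0.50) and the phosphatase inhibitor Ppp1r1a (-1.10 ± 0.44) followed. The largest positive means under the same limits were those of Cd28, a costimulatory receptor of T cells (1.84 ± 0.49), Mss51 (1.77 ± 0.55), Tph1 (1.57 ± 0.58), the matrix protein nephronectin, Npnt (1.47 ± 0.43), and Syt9 (1.45 ± 0.69). After them came the spindle protein Tpx2 (1.44 ± 0.41), Musk, the receptor kinase that organizes the neuromuscular junction (1.34 ± 0.18), and Atp13a5 (1.29 ± 0.21). All 16 had 1 sign at all 6 ZT, and Pla2g5, Mcm6, Tpx2, Musk and Atp13a5 were called at each ZT in the authors' deposited tables. By Stouffer's sum the largest adjusted p was 0.024, for Ighg2c, which passed no more without ZT4 (0.0885), ZT12 (0.0599) or ZT20 (0.0944). Ighg2c and Tph1 were called at 0 single ZT.

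Clock genes had small PER2 means. Clock (0.24 ± 0.15), Cry1 (0.15 ± 0.12), Nfil3 (0.27 ± 0.25), Rora (0.17 ± 0.15), Bhlhe41 (0.26 ± 0.10) and Hlf (0.19 ± 0.20) were positive, and Per3 (-0.28 ± 0.21) and Tef (-0.14 ± 0.07) negative. Arntl stood at 0.04 ± 0.27 and did not pass. The call of Cry1 was lost without ZT4 (adjusted p 0.0558) and that of Nfil3 without ZT20 (0.148). In the list of clock activators and genes in phase with Arntl, 4 of 6 were positive, 1 negative and 1 did not pass, with 5 past the threshold adjusted over the list alone. In the list of clock repressors and output genes, 3 of 12 were positive, 2 negative and 7 did not pass, with 5 past it adjusted over the list alone. The 3 positive ones include Per2, the targeted gene. Neither list passed camera (adjusted p 0.128 and 0.465).

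In PER2, 4 metabolic lists and those of interferon, endothelial, red blood cell and ribosomal protein genes passed camera in the negative direction. Of 22 genes of fatty acid oxidation, 10 were negative and 0 positive (adjusted p 0.00375, and adjusted p = 0.809 with an estimated correlation), with 11 past the threshold adjusted over the list alone. Examples are the enzymes Echs1 (-0.24 ± 0.17) and Eci1 (-0.25 ± 0.20), and Slc25a20 (-0.16 ± 0.18) and Cpt2 (-0.14 ± 0.13) of the carnitine shuttle. Of 25 nuclear-encoded genes of oxidative phosphorylation, 9 were negative and 0 positive (adjusted p 0.00694, and adjusted p = 0.809 with an estimated correlation, 11 adjusted over the list alone), among them Cox6a2 (-0.28 ± 0.25), Atp5b (-0.15 ± 0.16), Sdhd (-0.14 ± 0.08) and Ndufv1 (-0.13 ± 0.15). In lipid uptake and storage, 6 of 17 were negative and 1 positive (adjusted p 0.0143, and adjusted p = 0.809 with an estimated correlation, 10 adjusted over the list alone). Plin3 (-0.85 ± 0.30), Angptl4, an inhibitor of lipoprotein lipase (-0.81 ± 0.63), and Plin2 (-0.21 ± 0.10) were negative and Vldlr positive (0.32 ± 0.21). In branched-chain and other amino acid metabolism, 8 of 20 were negative and 1 positive (adjusted p 0.0202, and adjusted p = 0.809 with an estimated correlation, 11 adjusted over the list alone), with Bcat2 at -0.32 ± 0.21, Ivd at -0.21 ± 0.11, Mccc2 at -0.20 ± 0.11 and the amino acid transporter Slc38a2 at 0.48 ± 0.16.

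Of 11 genes of interferon response and antigen presentation, 7 were negative and 0 positive (adjusted p 0.00375, and adjusted p = 0.809 with an estimated correlation, 9 adjusted over the list alone), among them the peptide transporter Tap1 (-0.43 ± 0.29), Gbp2 (-0.38 ± 0.23), H2-K1 (-0.30 ± 0.15) and H2-D1 (-0.25 ± 0.18). Of 12 endothelial markers, 4 were negative and 0 positive (adjusted p 0.0143, and adjusted p = 0.809 with an estimated correlation, 6 adjusted over the list alone): Cldn5 (-0.34 ± 0.35), Esam (-0.14 ± 0.14), Cdh5 (-0.12 ± 0.06) and Pecam1 (-0.09 ± 0.08). All 5 red blood cell genes were negative (adjusted p 0.0297, and adjusted p = 0.809 with an estimated correlation, 5 adjusted over the list alone), with Hba-a1 at -0.48 ± 0.53, Hba-a2 at -0.47 ± 0.57, Hbb-bs at -0.49 ± 0.59 and Hbb-bt at -0.49 ± 0.58. Of 24 ribosomal protein genes, 1 passed, Rpl3 (-0.12 ± 0.08), and 0 adjusted over the list alone, while the list as a whole passed (adjusted p 0.0202, and adjusted p = 0.82 with an estimated correlation). The alpha and the beta globin genes, and H2-K1 and H2-D1, are close copies whose reads can be split between them, so single values are uncertain.

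These PER2 list results depended on the 2 ZT with the length trend. Oxidative phosphorylation genes had a median of -0.34 at ZT4 and -0.28 at ZT12, and 0.12 at ZT0. Without ZT4 alone, oxidative phosphorylation (adjusted p 0.118), amino acid metabolism (0.0656), ribosomal proteins (0.387) and red blood cells (0.0652) no longer passed, nor did ribosomal proteins (0.119) and red blood cells (0.0728) without ZT12 alone. Of the genes named from these lists, Slc25a20 (0.0623), Cpt2 (0.0611), Atp5b (0.084), Ndufv1 (0.0888), Cox6a2 (0.11), Cdh5 (0.0603), Pecam1 (0.108), Rpl3 (0.0961), Hba-a2 (0.106), Hbb-bs (0.104) and Hbb-bt (0.0765) lost their call without ZT4. Without ZT12 the calls of Cox6a2 (0.0633), Ndufv1 (0.0523), Pecam1 (0.201) and Rpl3 (0.105) were lost, without ZT8 those of Cdh5 (0.0526) and Pecam1 (0.16), without ZT20 that of Pecam1 (0.0578), and without ZT0 that of Rpl3 (0.078). Without ZT4 and ZT12, interferon (adjusted p 0.000222) and endothelial genes (0.0209) were the 2 of these 8 lists that still passed, tenocyte (0.000222) and fibroblast genes (0.0251) passed as well, and fatty acid oxidation (0.105) and oxidative phosphorylation (0.867) did not. After the length and GC correction 7 of the 8 passed, ribosomal proteins being the exception (0.219).

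The PER2 effect differed between ZT for 6 genes by Cochran's Q. A cosine of 24 h called 4 genes, and Q on z values 4. Only a change of amplitude 1.0 was simulated, so smaller ones may have been missed. Nr1d1 (adjusted p of Q 7.05e-05) was at 0.50 at ZT4 and -0.91 at ZT20 in the authors' deposited tables. In the same authors' deposited tables the adrenergic receptor Adra1a went from -0.79 at ZT0 to 0.35 at ZT16 (adjusted p of Q 0.00171). Pdk4, a kinase that inhibits pyruvate dehydrogenase, went from 1.66 at ZT0 to -1.17 at ZT8 in the authors' deposited tables (adjusted p of Q 0.0272). Ccs, the copper chaperone for superoxide dismutase, was lowest at ZT4 (-0.71) in the authors' deposited tables (adjusted p of Q 0.0312). The remaining 2 were Capn11 and Slc37a1 (both 0.0142), expressed below 1 CPM and outside the naming rule. Next in order and not past the threshold were Fgf9 and Tbc1d7 (both 0.054).

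The mean effects of the 2 knockouts ran opposite in the deposited directions. Among the 11436 genes measured in both, 1300 were positive and 1245 negative in PER2, and 2441 rose and 2509 fell in RORA. Genes positive in PER2 and down in RORA numbered 789, where 285.2 would be shared by independent lists (odds ratio 7.55, one-sided Fisher's exact p 2.2e-232), and genes negative in PER2 and up in RORA 611, where 265.7 would be (odds ratio 4.4, p 3.4e-119). Genes with the same sign numbered 123 (up, 277.5 in independent lists) and 115 (down, 273.1). So 85.5% of the genes called in both sets had opposite signs. Across genes, Pearson's r of the mean fold changes was -0.454 and Spearman's rho -0.414, and each of the pairs of a PER2 and a RORA ZT had an r between -0.405 and -0.189. Genes are not independent replicates, so these p-values describe the lists. The 2 sets share no controls. With the PER2 direction unstated, the signs show a relation between the sets but not whether it is of like or opposite effects of gene loss.

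**Figure D5:**
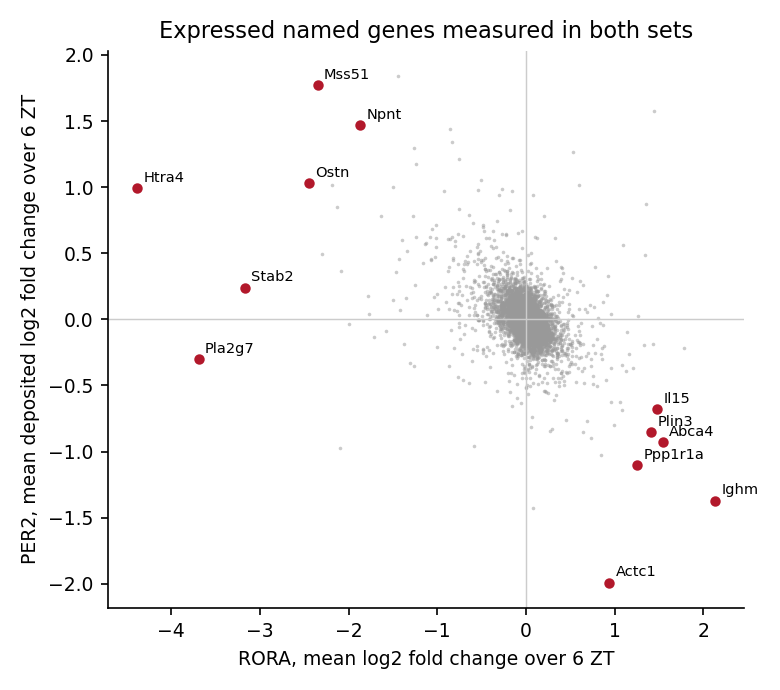
Mean log2 fold change over 6 ZT in PER2, in the deposited direction (vertical axis), against that in RORA (horizontal axis). Grey points are expressed named genes measured in both sets and red points the 12 with the highest and lowest differences. Mss51 lies at 1.77 in PER2 and -2.35 in RORA, and Plin3 at -0.85 and 1.41.

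Differences between the knockouts were tested in both readings. As deposited, the mean effects differed for 4569 genes, with the PER2 sign reversed for 2195, and either way for 1517, of which 938 had the larger change in RORA and 579 in PER2. The RORA fold changes may be shrunken and come from another kind of test than those of PER2. Sizes in the 2 sets are therefore not strictly alike, and these counts may depend on that. The highest differences as deposited (PER2 minus RORA, ± standard error) were those of Htra4 (5.35 ± 0.18), Mss51 (4.13 ± 0.25), Ostn (3.48 ± 0.14), Stab2 (3.41 ± 0.09), Pla2g7 (3.38 ± 0.09) and Npnt (3.34 ± 0.12). The lowest were those of Ighm (-3.45 ± 0.26), Actc1 (-2.97 ± 0.21), Abca4 (-2.44 ± 0.18), Ppp1r1a (-2.34 ± 0.09), Plin3 (-2.26 ± 0.09) and Il15 (-2.15 ± 0.10). With the sign reversed the order changed, to 3.97 for Pla2g7, 3.37 for Htra4, 2.93 for Stab2, 1.4 for Ostn and 0.38 for Npnt. Of those lowest as deposited, Il15 stood at -0.81, Ighm at -0.79, Abca4 at -0.64 and Plin3 at -0.58 when reversed, and Actc1 turned to 0.98. These 10 passed in both readings, and Mss51 (0.59, adjusted p 0.0809) and Ppp1r1a (-0.17, adjusted p 0.214) did not pass when reversed. Among clock genes, Arntl differed by 1.53 ± 0.08 as deposited and by 1.43 reversed, Cry1 by 0.82 ± 0.05 and 0.54, Bhlhe41 by 1.52 ± 0.06 and 1.00, and Hlf by 1.18 ± 0.06 and 0.79. Clock (0.21 and -0.26), Per2 (0.36 and -0.38) and Per3 (-0.32 and 0.25) turned sign, and Nfil3 (adjusted p 0.108), Dbp (0.112), Nr1d2 (0.0882) and Tef (0.929) differed as deposited and did not pass when reversed, while Usp2 passed only when reversed (-0.10, adjusted p 0.0665, and -0.13, adjusted p 0.0249).

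Of 36 lists, 10 differed between the knockouts as deposited. Those with the smallest adjusted p were nuclear oxidative phosphorylation (median difference -0.28, adjusted p 6.03e-07) and the tricarboxylic acid cycle (-0.31, adjusted p 0.000207), lower in PER2 than in RORA in the deposited direction (adjusted p = 0.701 for each with an estimated correlation). With the PER2 sign reversed 5 lists differed, and 2 differed either way. Oxidative phosphorylation was not among them (-0.08 reversed, adjusted p 0.103). The tricarboxylic acid cycle kept its direction (-0.11, adjusted p 0.035), while interferon genes turned from -0.39 (adjusted p 0.0314) to 0.20 (adjusted p 0.045). With an estimated correlation camera called 0 lists as deposited (smallest adjusted p = 0.701), and 2 had an unadjusted p under 0.05. With the sign reversed it called 0 as well (smallest adjusted p = 0.84, and 0.859 for the tricarboxylic acid cycle and for interferon genes), and 1 had an unadjusted p under 0.05.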

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

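The test of effects between ZT (Cochran's Q) was fixed in advance. The tests of length and GC content, of the targeted chromosomes, of the PER2 direction, of the precision at ZT4, of red blood cells and of satellite-like gene models were chosen only after the patterns were seen, the first 2 of them before their own results.

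Effects that differed between ZT were few in PER2, with 6 genes, and many in RORA, with 1565, though whether the counts differ between the knockouts was not tested. On the deposited scale, a simulated shift of 0.25 in the mean was called in 69.1% of cases in PER2 and in 95.8% in RORA. RORA fold changes may be shrunken, so the same shift need not stand for the same true change in both sets. A change with ZT was simulated at an amplitude of 1.0 only, so smaller ones may be missed in PER2. The span from the highest to the lowest log2 fold change over the 6 ZT was 1.41 for Nr1d1, 1.14 for Adra1a, 2.83 for Pdk4 and 0.70 for Ccs in PER2. All other spans are from RORA. Among clock genes it was 1.85 for Arntl, 0.98 for Nr1d1, 0.75 for Cry1, 0.57 for Bhlhe41, 0.53 for Hlf, 0.45 for Rora itself, 0.43 for Bhlhe40, 0.36 for Nr1d2 and 0.18 for Tef. Bhlhe40 had no call of its mean. Among the genes with the largest means it was 2.05 for Odf3l2, 1.06 for Ighm, 0.98 for Srrm4os, 0.97 for Shc2, 0.77 for Pla2g7, 0.56 for Stbd1, 0.55 for Itga4 and 0.46 for Aurka.

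In carbohydrate and fat metabolism the span in RORA was 0.28 for Eno3, 0.17 for Pdk2, 0.11 for Pdhb, 0.51 for Acsl1, 0.33 for Cpt2, 0.26 for Eci1, 0.22 for Eci2, 0.51 for Gpam, 0.41 for Plin4 and 0.64 for Srebf1. Nr4a3, an orphan nuclear receptor induced by activity, spanned 2.34, from 0.13 at ZT0 to 2.47 at ZT16 in the authors' deposited tables. At ZT8 Nr4a3 was at 0.59 with an error of 0.42 and a deposited adjusted p of 0.00616, smaller than that ratio gives. Shrinkage may thus have differed between ZT and stretched such RORA spans. Among mitochondrial genes the span was 0.14 for Atp5b, 0.20 for Idh3a, 0.23 for Pcx, 0.17 for Sucla2, 0.27 for mt-Cytb and 0.29 for mt-Nd2, of which the last 2 had means of 0.07 and 0.06 and both signs. Contractile and calcium handling genes spanned 1.07 for Casq2, 0.16 for Tnnc2, 0.34 for Actn3, 0.12 for Tnni2, 0.37 for Mylpf, 0.21 for Asph, 0.30 for Jph2 and 0.25 for Trdn. Genes of atrophy and growth control spanned 0.87 for Fbxo32, 0.51 for Trim63, 0.59 for Mstn and 0.51 for Gadd45a. Stress and antioxidant genes spanned 0.49 for Hspb6, 0.28 for Hsph1, 0.41 for Ppp1r15a, 0.19 for Prdx6 and 0.31 for Gpx4. Further spans were 0.44 for Odc1, 0.61 for Smox, 0.48 for H2-D1, 0.25 for Cdh5, 0.27 for Egfl7, 0.71 for Cpeb1 and 1.82 for Cdh4.

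The opposite signs of the PER2 and RORA means were the first pattern weighed (r -0.447 over 8500 expressed named genes). A shared trend with transcript length or GC content is argued against, since r was -0.434 with both regressed out of both sets. Variation linked to the targeted loci is argued against too as the source of r, which was -0.459 without chromosomes 1 and 9, which hold Per2 and Rora. This covers r across genes only. Single genes on these chromosomes were not tested for linked variation, so their values may include it. Tables written in opposite directions remain open: Per2 had a mean of 0.37, too small to settle the direction in a deletion that need not remove the whole transcript. A biological opposition of the 2 knockouts may hold only if the PER2 tables are knockout over control. In either reading, with CTRL given as wild type, loss of the targeted gene cannot be told from other differences between MKO and CTRL mice.

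The excess of PER2 calls at ZT4 was the second pattern (1586 calls, and 105 to 432 at other ZT). Smaller errors in the authors' tests at ZT4 are argued against, since the median derived error there was 1.02 times that of the other ZT. From ZT0 to ZT16 that median stayed between 0.135 and 0.137. It may thus not follow the spread among the mice of a single ZT, so their own precision at ZT4 stays open. A different share of red blood cells was predicted to move muscle genes the other way. Nuclear oxidative phosphorylation genes had a median of -0.34, the sign of the globin genes, with 25 of 25 below 0. The named globin genes, however, had a mean log2 CPM of 4.96 (Hba-a2) to 6.23 (Hbb-bs), a small part of the counts. A change in them could hardly move muscle genes either way, and the length trend at ZT4 could give that sign. The sign therefore cannot decide, and a red blood cell difference is not excluded. A trend with transcript length or GC content could account for much of it, since 34.2% of the ZT4 calls were still called after its removal, but 705 genes were then called at ZT4, above the highest corrected count of another ZT (335 at ZT0), so it may not be the whole cause. RNA quality and an effect of PER2 loss at that time remain open and untested.

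The third pattern was 13 predicted gene models with PER2 means of -7.18 to -10.16, all negative at all 6 ZT, which the naming rule leaves out. A few features taking most of the counts are argued against, since the models hold 0.015% of the deposited CPM. By sequence 10 of the 13 share at least 50% of their 31-base words with the others (median 76.8%), so the 13 may stand for few sequences. That overlap does not depend on the fold changes, so reads shared between near-identical copies stay open as a cause of the values. The one model also listed in RORA, Gm10800, had a positive mean there (6.40 ± 0.51, at a mean normalized count of 11.6), opposite to its PER2 mean in the deposited direction only. No biological explanation was tested.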

How the results depend on the processing

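Chosen only after the result was seen were the tests without ZT4 and ZT12, with the length and GC correction, with Q on z values, with the derived error, with Stouffer's sum in both sets and with the PER2 sign reversed, and all other settings were fixed before the data were examined. A minimum of 1.5-fold left 199, 471, 136, 189 and 120 PER2 genes at ZT0, ZT4, ZT8, ZT12 and ZT20, and 567, 621, 507, 459, 419 and 543 RORA genes from ZT0 to ZT20, by its construction. With the length and GC correction 705 PER2 genes were called at ZT4 and 273 at ZT12, of which 542 and 222 were also called without it. The PER2 mean called 1092 genes with limma and 1379 without ZT4 and ZT12, and 1873 (without ZT4) to 2796 (without ZT16) with 1 ZT left out. The RORA mean called 4564 genes with random effects, 7519 with Stouffer's sum and 4839 to 5295 with 1 ZT left out. The RORA change with ZT fell to 772 genes with a 24 h cosine and rose to 2617 with Q on z values. With an estimated correlation camera called 0 lists in PER2 (1 at an unadjusted p under 0.05), 0 in RORA and 0 for their difference. PER2 lists numbered 6 (without ZT4) to 13 (without ZT0) with 1 ZT left out and 4 without ZT4 and ZT12, and RORA lists 6 to 10. With the PER2 sign reversed, 2195 genes and 5 lists differed, and the differences of Actc1 (0.98), Clock (-0.26), Per2 (-0.38), Per3 (0.25) and interferon genes (0.20) reversed. The cause was not tested where the construction does not show it. Of 91 named PER2 genes 45 lost their call with limma, 22 with random effects, 39 without ZT4 and ZT12, 18 without ZT4, 15 without ZT8 and 15 with the length and GC correction. Of 95 named RORA genes 5 did with limma and 5 with random effects. In either set 0 named genes with a call passed with the opposite sign under another setting. Sign changes without a call in both settings were not counted. Of 62 named genes whose effect changed with ZT, 30 lost that call with the cosine. The overlaps kept their direction at a threshold of 0.01. No paired analysis was possible because the tables hold no values per library, and library numbers run on through the groups. For the same reason normalization of counts, count filters, pseudocounts and leaving out single libraries were not run, nor regrouping of libraries. Whole ZT tables were instead reversed in sign. Of 32 ways only the deposited one (1) called 2792 genes in PER2 (highest other 1817), and only 1 called 5449 in RORA (highest other 4334). That is a share of 1 in 32, the smallest these can give. It restates that the ZT of a set agree, as their correlations show (r of 0.2 to 0.718 in PER2 and 0.811 to 0.886 in RORA). No mice were moved between groups, so it cannot test differences between the mice of MKO and CTRL. Depth per library is unknown, which limits what missing calls show.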

Other observations

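The pathway and marker lists in this part were fixed in advance, and the choice of the polyamine genes to lead it, the RORA trend with GC content and the counts of markers at single ZT came only after the result was seen.

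Single polyamine genes were called in both sets. Odc1, the rate-limiting enzyme of polyamine synthesis, fell by 1.49 ± 0.19 in RORA MKO and had a PER2 mean of 1.00 ± 0.41. Smox, which oxidizes spermine, fell by 1.14 ± 0.23 in RORA MKO, and Amd1, which makes the aminopropyl donor, had a PER2 mean of 0.45 ± 0.18. Their list, with nicotinamide and ketone genes, passed in neither set (adjusted p 0.251 in RORA, with 2 of 14 up and 4 down, and 0.858 in PER2, with 4 positive and 2 negative). Mstn, the growth inhibitor myostatin, fell by 0.54 ± 0.20 in RORA MKO with Fbxo32 (-0.55 ± 0.31), and Mstn (0.50 ± 0.22) and Cdkn1a (0.27 ± 0.35) were positive in PER2, though Cdkn1a not without ZT8 (adjusted p 0.353), while the atrophy list passed in neither (0.906 and 0.465). Musk fell by 0.84 ± 0.15 and Gadd45a rose by 0.48 ± 0.19 in RORA MKO, and Gadd45a was negative in PER2 (-0.40 ± 0.21), with the denervation list at 0.623 in RORA and 0.128 in PER2. Among fat synthesis genes Srebf1 (-0.87 ± 0.23) and Me1 (-0.83 ± 0.06) fell in RORA MKO, and in PER2 Scd2 was negative (-0.55 ± 0.25) and Me1 positive (0.24 ± 0.14), with list adjusted p of 0.0551 and 0.828.

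In carbohydrate metabolism, Aldoa (0.31 ± 0.03) and Eno3 (0.26 ± 0.10) of glycolysis, Pdk2 (0.29 ± 0.06) and Pdhb (0.15 ± 0.04) of pyruvate oxidation and Ugp2 of glycogen synthesis (0.49 ± 0.06) rose in RORA MKO, and the glycogenin gene Gyg fell by 0.33 ± 0.04. The list adjusted p in RORA were 0.6 for glycolysis, 0.0676 for glucose uptake and pyruvate oxidation and 0.0964 for glycogen. In PER2, Hk2 (0.25 ± 0.24), Pfkm (0.11 ± 0.08), Akt2 (0.15 ± 0.13) and Ugp2 (0.22 ± 0.09) were positive and Pdk2 (-0.14 ± 0.07) and the glycogen-targeting Ppp1r3b (-0.71 ± 0.20) negative, with list adjusted p of 0.651, 0.947 and 0.206 in the same order. Without ZT8 the PER2 calls of Hk2 (0.104), Pfkm (0.0511) and Akt2 (0.154) were lost. Nr4a3 (1.09 ± 0.90) and Ppard (0.17 ± 0.05) rose in RORA MKO, and Ppargc1a (0.22 ± 0.24) and Nr4a1 (0.19 ± 0.22) were positive in PER2, in a list of PPAR and PGC-1 regulators at 0.0551 and 0.507. The calls of Ppargc1a (0.162) and Nr4a1 (0.257) were lost without ZT8, and that of Nr4a1 also without ZT0 (0.0777) or ZT16 (0.118). Gpt2 (0.64 ± 0.10) and Bckdk (0.21 ± 0.02) rose in RORA MKO, where amino acid metabolism as a list did not pass (0.623). In PER2 the tricarboxylic acid cycle did not pass (0.0936), with Pcx at 0.42 ± 0.08 and Idh2 at -0.34 ± 0.21.

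The slow sarcomere list passed in neither set (0.6 in RORA and 0.487 in PER2), with Casq2 at 0.41 ± 0.38 in RORA and -0.19 ± 0.26 in PER2, and 1 of 12 members past the threshold for the mean in each. At single ZT its RORA members moved in both directions, with 11 of 12 called up at ZT0 (median 0.62) and 6 called down at ZT4 (-0.19) in the authors' deposited tables. In PER2 the fast sarcomere (0.946), with Mybpc2 (0.14 ± 0.08) and Actn3 (-0.10 ± 0.11), and calcium handling (0.143), with Asph (0.19 ± 0.10) and Camk2b (0.13 ± 0.09), did not pass. Actc1 rose by 0.94 ± 0.37 and Myod1 by 0.14 ± 0.14 in RORA MKO, and Pax7 was negative in PER2 (-0.17 ± 0.21), in a myogenic list at 0.516 and 0.923. The PER2 calls of Mybpc2 (0.137), Actn3 (0.231) and Camk2b (0.0578) were lost without ZT4, those of Mybpc2 (0.0612), Camk2b (0.0762), Casq2 (0.0996) and Pax7 (0.0557) without ZT8, those of Actn3 (0.206), Casq2 (0.254) and Pax7 (0.0914) without ZT0, those of Actn3 (0.134) and Casq2 (0.23) without ZT12, and that of Pax7 without ZT16 (0.162) or ZT20 (0.298). Mitochondrially encoded genes did not pass (0.469 and 0.946), with mt-Cytb (0.07 ± 0.10) and mt-Nd2 (0.06 ± 0.10) up in RORA MKO, calls that were lost without ZT8 (0.0989 and 0.159). The heat shock list stood at 0.906 in RORA, with Hspb6 (0.39 ± 0.17) and Hsph1 (-0.25 ± 0.12), and at 0.0515 in PER2, with Hsph1 (0.24 ± 0.16) and Hsp90aa1 (0.18 ± 0.12), where the length and GC correction took it past the threshold (0.0298).

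The antioxidant list passed in neither set (0.623 in RORA and 0.128 in PER2). Gpx4 rose by 0.23 ± 0.12 and Prdx6 fell by 0.25 ± 0.08 in RORA MKO, and the secreted peroxidase Gpx3 (-0.81 ± 0.28) and Gstm2 (-0.43 ± 0.23) were negative in PER2. In autophagy (0.722 and 0.901) Map1lc3b rose by 0.16 ± 0.03 and Lamp1 fell by 0.12 ± 0.03 in RORA MKO, and Ctsb (-0.19 ± 0.11) and Ctsl (-0.19 ± 0.15) were negative in PER2. In the integrated stress response (0.992 and 0.66) Atf5 rose by 0.12 ± 0.03 and Ppp1r15a fell by 0.18 ± 0.17 in RORA MKO, and Sesn2 was positive in PER2 (0.20 ± 0.16). Jun fell by 0.28 ± 0.15 in RORA MKO and Dusp1 was positive in PER2 (0.26 ± 0.21), with immediate early genes as a list at 0.605 and 0.465. Sesn2 (0.076) and Dusp1 (0.18) lost their call without ZT8, and Dusp1 also without ZT4 (0.104), ZT12 (0.0574), ZT16 (0.147) or ZT20 (0.0539). Interferon genes did not pass in RORA (0.31), where H2-D1 rose by 0.14 ± 0.18, a call that rested on ZT4 (adjusted p 0.103 without it).

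Tested on the mean over ZT, other cell types gave no list call in RORA beyond endothelial cells, at adjusted p of 0.6 for fibroblasts, 0.623 for tenocytes, 0.0551 for smooth muscle and pericytes, 0.31 for macrophages and leukocytes, 0.725 for white and 0.0551 for brown adipocytes, 0.181 for red blood cells, 0.623 for Schwann cells and 0.906 for satellite cells. At single ZT many of these markers were called in the authors' deposited RORA tables. At ZT20, 10 of 10 Schwann cell (median 0.74), 9 of 9 smooth muscle and pericyte (0.19), 7 of 8 white adipocyte (0.53) and 5 of 5 red blood cell genes (0.29) were up. Other lists had fewer up then, with 4 of 16 fibroblast, 3 of 14 macrophage and leukocyte and 0 of 9 tenocyte genes. Of all genes, 32.2% were called at ZT20, up or down. Schwann cell genes had 5 down at ZT0 and 6 at ZT4. Of white adipocyte genes 5 were down and 1 up at ZT0, and 3 down and 2 up at ZT4. Lists were not tested at single ZT. In PER2 the values were 0.141 for fibroblasts, 0.176 for tenocytes, 0.325 for smooth muscle and pericytes, 0.176 for macrophages and leukocytes, 0.764 for neutrophils, 0.128 for white adipocytes, 0.154 for Schwann cells and 0.325 for satellite cells. Lymphocyte markers had 0 measured genes in either set, neutrophil markers 2 in RORA and brown adipocyte markers 2 in PER2, too few to test. The RORA fold changes had a Spearman's rho with GC content between 0.08 and 0.19 at ZT0 to ZT16 and of 0.37 at ZT20, the ZT with the most calls. Of the 609 RORA genes with a 24 h cosine among those that changed with ZT, 168 had the fitted peak of the fold change between ZT0 and ZT4 and 56 between ZT8 and ZT12.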
